A study of Homo sapiens with 56 samples.

How the data were processed

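RNA of 56 THP-1 cultures was measured on Affymetrix U133 arrays, 4 in each of 14 groups of SB, treatment and time. The authors deposited MAS5 signals, an intensity on a linear scale, which per the submitters' processing notes are signal values of the MAS5 software; its version is not given in the sources used here. The 2% trimmed mean of each deposited array was near 100. Each array was divided by its 678th highest signal, the 97th percentile that the deposited description names, and log2 values were taken. Of 22283 probe sets 68 control probe sets were left out, and 22215 were tested without a filter on signal. Of the tested probe sets, 19065 carried 1 gene symbol, of 11963 genes in all, 1043 carried several and 2107 none, and only those with 1 symbol were named. No pair of arrays held the same values.

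R 4.3.3 with limma 3.58.1 fitted 1 linear model per probe set to all 56 arrays, with a term for each batch, a level for each SB arm at time 0 and 4 slopes over time in hours (GSH, GSNO, SB with GSH and SB with GSNO). This is a blocked analysis of covariance with a common time 0 in each SB arm and 47 residual degrees of freedom, and variances were moderated with a trend on mean signal. Contrasts of the slopes were the GSNO effect in each SB arm, the SB effect with GSH and with GSNO, and their interaction; an F-test covered any difference among the 4 slopes. SB at time 0 was compared in the 8 arrays of that time, with batch. Levels at 45, 90 and 180 min came from a model with 1 mean per group and batch. All tests were two-sided, p-values were adjusted over all tested probe sets by the method of Benjamini and Hochberg, and 0.1 was the threshold. A half-life is the time in which the fitted slope takes the signal to 50%. Replicate numbers were taken as batches, as the labels state 4 batches. This pairing was checked on each array's deviations from the mean of its group. In 87 of 91 pairs of groups every correlation between arrays of the same number was above 0.1, and the median was 0.428. The median for other numbers was -0.141, a negative value that follows from centring on group means and adds no evidence. The number of arrays limits the precision of each slope.

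The model, the comparisons, 20 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule names, for each comparison, up to 12 genes per direction with the largest difference, or the smallest p for the F-test. Their probe sets had to pass the threshold, carry 1 symbol, lie above the median signal and keep their sign without each batch. Where fewer than 5 passed, all that passed were named without the filter on signal, and 17 further genes were given whatever their result. From each list the members named are among the 4 with the smallest p; genes taken from it in lists that did not pass were chosen by the same order. Other probe sets of a named gene are given where they lie above the median signal and have the opposite sign, and for some genes also where the sign is the same. Of 47 such other probe sets above the median signal 38 had the same sign, some with a value near 0. The lists were LPS-induced cytokines, immediate-early transcription factors, NF-kappa-B pathway genes, MAPK phosphatases, MAP kinase cascade components, mRNA-binding and mRNA-decay factors, NRF2 and antioxidant genes, heat shock proteins, interferon-induced genes, apoptosis regulators, stress genes of the endoplasmic reticulum and ATF4, glycolysis and hypoxia genes, cell cycle regulators, regulators of phosphatases, ubiquitin and small GTPases, monocyte markers, markers of other cell types, housekeeping genes, ribosomal proteins, oxidative phosphorylation subunits and numbered zinc finger proteins. Each list of at least 5 measured genes, with the brightest probe set of each gene, was tested against all other genes with limma's camera at an inter-gene correlation of 0.01 and again with an estimated one, adjusted over the 20 lists. Members were also adjusted over their list alone. A list said to move up or down did so against all other genes, and its own median may lie near 0.

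The model was tested on simulated data with 200 changed probe sets, all above the median signal. It recovered 95.5% of changes of 0.5 log2 per h for the GSNO effect without SB, 98.5% with SB, 82.1% for the SB effect with GSH, 86.6% with GSNO and 80.6% for the interaction, with between 6.79% and 14.2% false calls. Of changes of 0.25 log2 per h it recovered 71.6%, 67.2%, 37.3%, 40.3% and 28.4%, in the same order. At time 0 it recovered 44.8% of changes of 1 log2. The simulated noise was independent between probe sets and between arrays. It holds no structure shared between probe sets, so recovery and false calls may differ in the real arrays.

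Alternatives were quantile normalization, median scaling, no further scaling, ribosomal protein genes as the reference, an offset before log2 (0.00547, the 20th percentile of signal), a filter on signal, for lists the mean of all probe sets of a gene, tests without moderation, no batch term or 1 per SB arm, array weights, free intercepts, levels at 180 min, a threshold of 0.05 and each batch left out. Others were added after the data were seen: the 9 arrays with a 3' to 5' ratio above 1.5 left out, the beta-actin ratio as a covariate and each array left out. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Sequence motifs of transcripts were not searched since no transcript sequences were at hand.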

Results

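THP-1 cells, a human monocytic leukaemia line, were stimulated for 4 h with lipopolysaccharide (LPS, 1 µg/ml), a bacterial product that induces many short-lived inflammatory messenger RNAs. Transcription was then blocked with actinomycin D (2.5 µg/ml) for 30 min, without or with 0.1 µM of a p38 MAP kinase inhibitor that the labels call SB. The cells next received 400 µM S-nitrosoglutathione (GSNO), a donor of nitric oxide, or the same concentration of glutathione (GSH) as its control, and were collected 45, 90 or 180 min later. Cells of each SB arm were also collected at 0 min. The 14 groups held 4 arrays each, 1 from each of 4 batches, which made 56 Affymetrix U133 arrays. The median signal of an array lay between 23.8 and 35.4, its 678th highest signal between 1047 and 1276, and the correlation between any pair of arrays between 0.872 and 0.962. A slope is the change of log2 signal per hour relative to that reference signal, so a negative slope is a fall relative to the reference while synthesis was blocked, and total mRNA per cell was not measured. The percent left at 180 min is given as mean ± SD of 4 batches. A p-value of a probe set measures the spread between these arrays that is left after the batch term. A camera p-value instead compares the genes of a list with all other genes, at a set or estimated correlation between genes. The number of arrays limits the precision of each value.

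Signs of RNA quality differed between arrays. The ratio of the 3' to the 5' control probe set was 0.896 at the median for GAPDH, with a range from 0.782 to 2.87, and 0.958 for beta-actin, with a range from 0.778 to 7.29. It was above 1.5 on 9 arrays. Without SB these were GSH at 45 min replicate 4, GSH at 180 min replicate 3 and GSNO at 90 min replicate 3. With SB they were time 0 replicate 4, GSH at 45 min replicate 1, GSH at 180 min replicates 3 and 4, and GSNO at 180 min replicates 1 and 3.

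**Figure D1:**
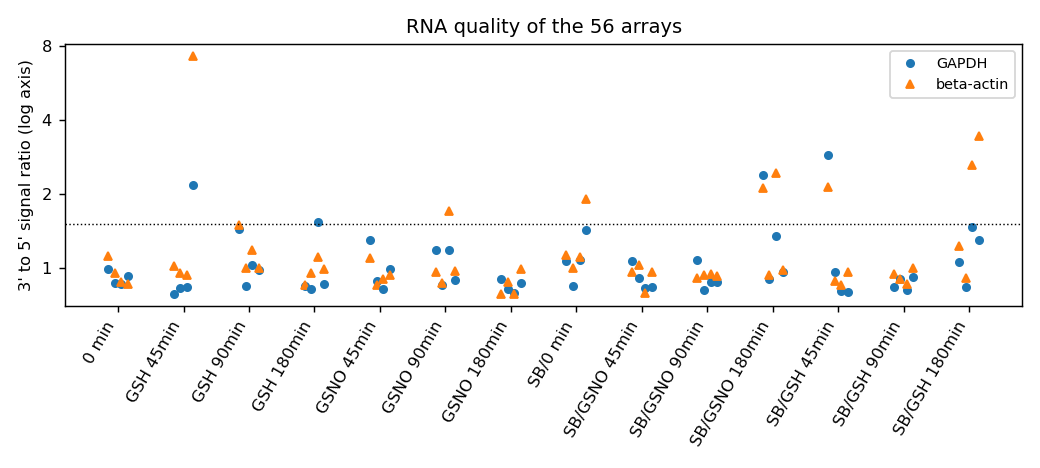
Ratio of the 3' to the 5' control probe set of GAPDH and of beta-actin on each of the 56 arrays, on a logarithmic axis, by group; 1 point is 1 array. The highest beta-actin ratio, 7.29, belongs to GSH at 45 min without SB, replicate 4.

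The first question was which transcripts fell relative to the reference after transcription was blocked. With GSH alone, PRP4K, SIAH2, RIOK2, RRS1 and CRKL had the lowest slopes among genes that met the naming rule. SIAH2, a ubiquitin ligase, had a slope of -1.47 ± 0.10 log2 per h (SE; adjusted p = 4.63e-17), a half-life of 40.9 min and 5.72% ± 2.1 left at 180 min (SD, n = 4). RIOK2, a kinase of ribosome assembly, had a half-life of 43.3 min with 6.11% ± 4.22 left, and CRKL, an adaptor protein, one of 45.7 min with 9.31% ± 5.39 left. CCN2, PTGER4, RNF139, GADD45B, CDYL, ID2 and CDK7 fell with half-lives between 47.1 and 53.0 min. PRP4K had a half-life of 40.7 min (slope -1.47 ± 0.15), while another bright probe set of this gene had a slope of 0.04. Another bright probe set of CRKL had a slope of -0.20 that did not pass in limma (adjusted p = 0.107). Signals that rose relative to the reference included CYP27A1 (0.62 ± 0.16, adjusted p = 0.00384), PTGDS (0.39 ± 0.09), XRCC2, CBL, HGD, GPC1, CST4, IL12B, HOXD1, CDK19, ARHGAP44 and KIF5A. For CYP27A1 the percent left varied widely, 814% ± 844.

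In limma, 2851 probe sets had a negative and 1077 a positive slope with GSH, together 3928 probe sets of 2879 genes. With GSNO 3359 fell and 449 rose, with SB and GSH 1693 fell and 276 rose, and with SB and GSNO 3362 fell and 766 rose. The share that rose depended on the scaling of the arrays. Falling and rising probe sets with GSH numbered 2565 and 2369 after quantile normalization, 2577 and 1437 after median scaling, 2552 and 2127 without further scaling, and 3794 and 219 with ribosomal protein genes as the reference. Slopes fitted from 45 min onward with a free intercept gave 1874 falling probe sets.

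Each list was tested against all other genes. Of 36 immediate-early transcription factors, which respond to stimulation within minutes, 17 fell with GSH, 0 rose and 19 did not pass (22 falling when adjusted over the list alone). BTG1 (-1.04 ± 0.07), CEBPD (-0.86 ± 0.06), CEBPB (-1.11 ± 0.08) and ID2 (-1.13 ± 0.09) were examples, and the list fell against all other genes (camera adjusted p = 1.13e-11, and adjusted p = 0.0595 with an estimated correlation). Of 33 protein phosphatase, ubiquitin and small GTPase regulators 16 fell and 2 rose (18 and 3 adjusted over the list alone), among them USP1 (-0.86 ± 0.05), SIAH2, FBXO28 (-0.60 ± 0.05) and PELI1 (-1.07 ± 0.09). Their camera adjusted p was 2.44e-07, and adjusted p = 0.0468 with an estimated correlation. Of 34 NF-kappa-B pathway genes 16 fell and 0 rose (18 falling adjusted over the list alone), including the inhibitor NFKBIE (-0.92 ± 0.06), TBK1 (-0.69 ± 0.06), RIPK2 (-0.63 ± 0.06) and NFKBIA (-1.08 ± 0.13). The camera adjusted p was 2.01e-06, and adjusted p = 0.095 with an estimated correlation.

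Further lists fell in camera, but their calls were lost with an estimated correlation. Among 15 MAPK phosphatases and ERK feedback inhibitors 9 fell and 1 rose (10 and 1 adjusted over the list alone), such as SPRED2 (-0.94 ± 0.07), DUSP7 (-0.82 ± 0.10) and DUSP6 (-0.90 ± 0.12), with an adjusted p of 0.000446 and adjusted p = 0.131 with an estimated correlation. Among 45 mRNA-binding and mRNA-decay factors 14 fell and 0 rose (19 and 2 adjusted over the list alone), such as CNOT2, a subunit of the deadenylase complex (-0.67 ± 0.05), HNRNPA1 (-0.70 ± 0.08) and ZFP36L2 (-0.71 ± 0.08), with an adjusted p of 0.000786 and adjusted p = 0.135 with an estimated correlation. Of 41 apoptosis regulators 15 fell and 3 rose (17 and 4 adjusted over the list alone). They included TNFRSF1A (-1.05 ± 0.08), BCL2A1 (-0.49 ± 0.04) and GADD45B (-1.17 ± 0.12), and the list had an adjusted p of 0.00137 and adjusted p = 0.135 with an estimated correlation. Of 48 cell cycle regulators 17 fell and 0 rose (18 and 1 adjusted over the list alone), with AURKA (-0.73 ± 0.07) and CDC25A (-1.05 ± 0.12) among them. The list had an adjusted p of 0.00137, and adjusted p = 0.283 with an estimated correlation. Of 33 endoplasmic reticulum and ATF4 stress genes 8 fell and 2 rose (11 and 2 adjusted over the list alone), XBP1 at -0.69 ± 0.06 and TRIB3 at -0.70 ± 0.06 (adjusted p = 0.0135, and adjusted p = 0.258 with an estimated correlation). Of 25 heat shock proteins and chaperones 7 fell and 0 rose (8 and 1 adjusted over the list alone), BAG3 at -0.69 ± 0.05 and DNAJB1 at -0.64 ± 0.08 (adjusted p = 0.036, and adjusted p = 0.131 with an estimated correlation). Of 41 MAP kinase cascade components 12 fell and 1 rose (13 and 3 adjusted over the list alone), MAP3K8 at -1.01 ± 0.11 and MAPK6 at -0.38 ± 0.05 (adjusted p = 0.073, and adjusted p = 0.398 with an estimated correlation). Above the median signal alone the calls of the stress genes and the heat shock proteins ended (adjusted p 0.281 each). That of the MAP kinase cascade also ended there (0.26), under quantile normalization (0.321) and without replicate 2 (0.115).

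The remaining lists went up against other genes or did not differ from them. Of 56 cytosolic ribosomal protein genes 16 rose and 2 fell relative to the reference (27 and 2 adjusted over the list alone), RPL12 at 0.15 ± 0.04 and RPL10A at 0.10 ± 0.03, while RPS27L, which responds to p53, fell at -0.23 ± 0.04. The list's camera adjusted p was 6.82e-06, adjusted p = 0.396 with an estimated correlation, and its direction turned after quantile normalization (adjusted p 0.391). Of 24 housekeeping genes 5 rose and 1 fell (8 and 2 adjusted over the list alone), GUSB at 0.20 ± 0.04 and TBP at -0.41 ± 0.06 (adjusted p = 0.00624, and adjusted p = 0.33 with an estimated correlation), a call that ended after quantile normalization (adjusted p 0.989). Of 31 monocyte and macrophage markers 7 rose and 1 fell (8 and 4 adjusted over the list alone), the cathepsins CTSB at 0.14 ± 0.03 and CTSS at 0.17 ± 0.05 and the receptor TLR2 at -0.26 ± 0.06 (adjusted p = 0.0216, and adjusted p = 0.117 with an estimated correlation). Of 66 oxidative phosphorylation subunits 12 rose and 9 fell (14 and 11 adjusted over the list alone), ATP5MG at 0.15 ± 0.03 and NDUFC1 at -0.16 ± 0.03 (adjusted p = 0.0885, and adjusted p = 0.565 with an estimated correlation). The LPS-induced cytokines and chemokines were split, with 5 of 37 rising and 5 falling (5 and 8 adjusted over the list alone), EBI3 at 0.26 ± 0.05 and TNFSF9 at -0.58 ± 0.08 (adjusted p = 0.885). So were the 33 NRF2 and antioxidant genes, with 8 rising and 8 falling (9 and 8 adjusted over the list alone), KEAP1 at -0.85 ± 0.08 and its partner NFE2L2 at -0.76 ± 0.07 (adjusted p = 0.885). Of 45 interferon-induced genes 6 rose and 10 fell (7 and 11 adjusted over the list alone), RIGI at -0.55 ± 0.06 (adjusted p = 0.885). Of 31 glycolysis and hypoxia-response genes 6 rose and 6 fell (8 and 8 adjusted over the list alone), LDHA at -0.51 ± 0.04 (adjusted p = 0.736). Of 212 numbered zinc finger protein genes 6 rose and 35 fell (8 and 40 adjusted over the list alone), ZNF274 at -0.58 ± 0.05 (adjusted p = 0.119). None of the 25 measured markers of lymphocytes, erythroid and non-haematopoietic cells passed in limma in either direction, KRT18 having the smallest p of them with 0.36 ± 0.20 (adjusted p = 0.251). The call of the oxidative phosphorylation subunits ended under quantile normalization (0.325), median scaling (0.102) and ribosomal protein scaling (0.769), with the mean of all probe sets of a gene (0.108) and without replicate 1 (0.2) or 4 (0.297), and that of the monocyte markers without the batch term (0.122).

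The genes given whatever their result had a range of slopes with GSH, and a slope that did not pass does not show that a transcript is stable. MYC fell with GSH with a half-life of 45.3 min, to 5.15% ± 1.78 at 180 min, and NFKBIA, the inhibitor of NF-kappa-B, with one of 55.6 min, to 11% ± 7.77. TNF fell with a half-life of 86.1 min, to 22.4% ± 11.6, and TAB2, an adaptor of the kinase TAK1, with one of 219 min, to 63.8% ± 8.7. Slopes with GSH did not pass for IL1B (0.00 ± 0.04), IL6 (0.08 ± 0.09), CXCL8 (-0.13 ± 0.09), PTGS2 (-0.13 ± 0.10), IER3 (-0.13 ± 0.06), ZFP36 (-0.33 ± 0.13), FOS (-0.34 ± 0.17), EGR1 (0.10 ± 0.08), DUSP1 (-0.11 ± 0.28) and HMOX1 (0.03 ± 0.05). ACTB had a slope of 0.10 ± 0.06 that did not pass and was -0.01 after quantile normalization. GAPDH rose at 0.14 ± 0.05 (adjusted p = 0.0333), and its slope of 0.08 with ribosomal protein genes as the reference did not pass (adjusted p 0.112). None of these 16 genes differed among the 4 conditions in limma, where the adjusted p was 0.66 for TNF, 0.785 for NFKBIA and 0.685 for MYC. MAPK14, the gene of p38 alpha, has no probe set assigned to a single symbol and was not analysed here.

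The next question was for which transcripts the rate of loss differed among GSH, GSNO, SB with GSH and SB with GSNO. ALAS1, the first enzyme of haem synthesis, had the smallest p (adjusted p = 2.85e-09). It was left at 56.1% ± 4.33 with GSH, 90.5% ± 5.22 with GSNO, 104% ± 18.2 with SB and GSH, and 60.5% ± 6.43 with SB and GSNO. SIAH2 followed the same order, with 5.72% ± 2.1, 20.7% ± 9.88, 29.6% ± 15.9 and 6.91% ± 4.91 left (adjusted p = 1.74e-06). The ubiquitin ligase KCMF1 was left at 55.2% ± 6.76, 71.6% ± 7.91, 84.1% ± 10.8 and 51.7% ± 11.9. PPP3CC, a catalytic subunit of calcineurin, was left at 38.8% ± 15.9, 57.8% ± 10.2, 70.2% ± 14.5 and 23.5% ± 13.1. CYTH2, an exchange factor for ARF GTPases, was left at 51.4% ± 14.3, 102% ± 16.4, 69.8% ± 26.7 and 25.4% ± 11.3. ELF4, SRSF7, MRPL15, QRSL1, ADRM1, USP1 and GRSF1 completed the 12 genes with the smallest p, with adjusted p-values up to 4.99e-05.

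The limma F-test selected 284 probe sets of 247 genes, of which 274 fell in at least 1 condition. Among these 274 the slowest loss was with SB and GSH for 215, with GSNO for 38, with GSH for 13 and with SB and GSNO for 8. The fastest loss was with SB and GSNO for 132 and with GSH for 112. Their median slope was -0.40 with GSH, -0.32 with GSNO, -0.18 with SB and GSH, and -0.41 with SB and GSNO. The count of 284 was 154 without SB with GSH at 180 min replicate 4 and 633 without SB with GSNO at 180 min replicate 3. It was 163 with ribosomal protein genes as the reference, 150 for levels at 180 min, 81 without the batch term, 4 with free intercepts, 103 without batch 2 and 138 without batch 4.

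**Figure D2:**
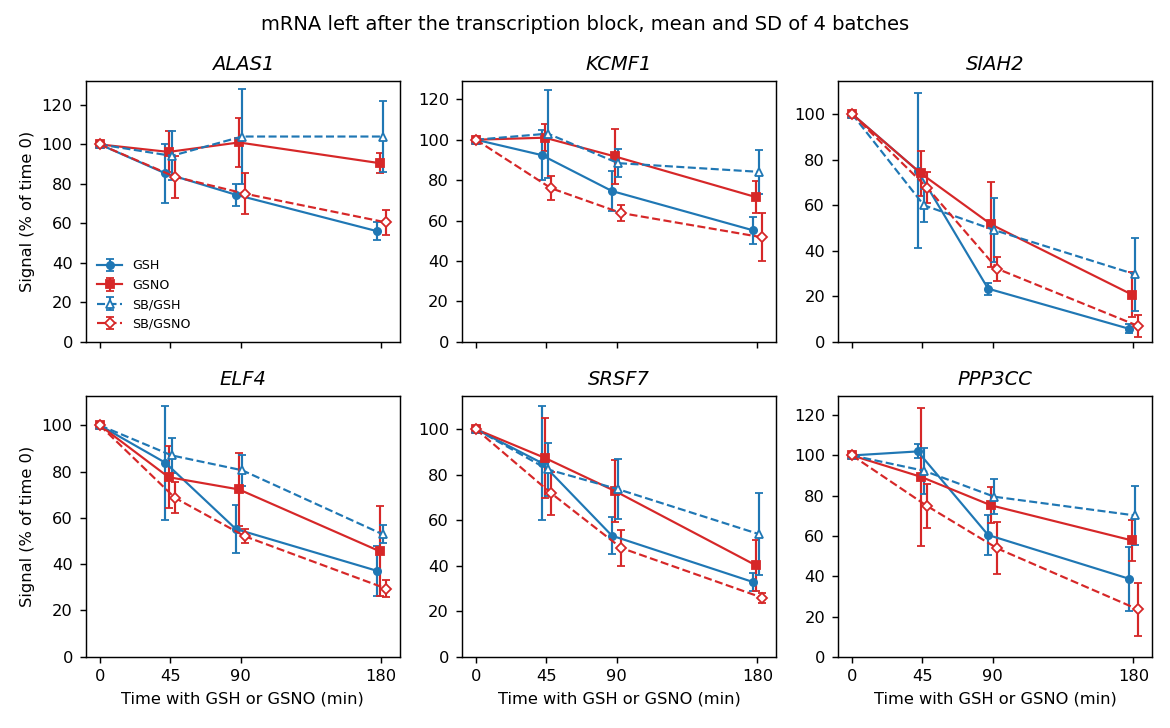
Percent of the time 0 signal left at 45, 90 and 180 min for ALAS1, KCMF1, SIAH2, ELF4, SRSF7 and PPP3CC, genes with different slopes. Lines join means and bars are SD of 4 batches. ALAS1 ended at 56.1% with GSH and 90.5% with GSNO, and at 104% and 60.5% with SB.

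Without SB, the comparison of GSNO with GSH asked whether nitric oxide changes transcript loss. SIAH2 fell more slowly with GSNO, by 0.59 ± 0.10 log2 per h (SE; adjusted p = 0.00169), and more of it was left in 4 of 4 batches. RIOK2 (0.59 ± 0.11), MEF2D, a transcription factor (0.52 ± 0.10), CEBPA, a myeloid transcription factor (0.37 ± 0.07), and ALAS1 (0.24 ± 0.03, adjusted p = 3.01e-05) also fell more slowly, each with more left in 4 of 4 batches. CEBPA was left at 60.7% ± 32.8 with GSNO against 28.8% ± 10.1 with GSH. EXOSC4, a subunit of the RNA exosome (0.61 ± 0.14), RNF19B (0.39 ± 0.09), MRPS2, RFC1, QRSL1, MRPL58 and SCCPDH passed in the same direction. Other bright probe sets had 0.30 and 0.16 for EXOSC4, 0.06 for RFC1, 0.03 for QRSL1 and 0.05 for SCCPDH, and did not pass. Another of RNF19B, the one named below for the SB effect with GSH, had 0.955 (limma adjusted p = 0.000298). Slopes were lower with GSNO for CDK13 (-0.77 ± 0.15), CACNB3 (-0.70 ± 0.17), ZNF506 (-0.56 ± 0.12), ACTN3 (-0.55 ± 0.10), NAT9, ZNF35, ID1 (-0.37 ± 0.09), MYL10 and the integrin ITGAM (-0.18 ± 0.04). Genes with a lower slope were named without the filter on signal, since too few passed it. Of the 21 genes named for this comparison 16 lay above the median signal. Those below it, CDK13 among them, all had a lower slope. For CDK13 the percent left was lower in 3 of 4 batches, and for ITGAM another bright probe set had 0.06.

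In limma 26 probe sets of 25 genes passed, 16 with a higher and 10 with a lower slope. The protein phosphatase, ubiquitin and small GTPase regulators moved up against other genes (camera adjusted p = 0.00371, and adjusted p = 0.559 with an estimated correlation), although SIAH2 alone of 33 passed, or 3 when adjusted over the list alone. PELI1 had 0.30 ± 0.09 and USP1 0.13 ± 0.05. Cell cycle regulators moved up against other genes (camera adjusted p = 0.00278, and adjusted p = 0.559 with an estimated correlation). Of them 0 of 48 passed, with 3 higher when adjusted over the list alone. PLK3 had 0.39 ± 0.10 and CDC25A 0.41 ± 0.12. NF-kappa-B pathway genes moved up (adjusted p = 0.0125, and adjusted p = 0.559 with an estimated correlation) with 0 of 34 passing and 2 higher when adjusted over the list alone, RELB at 0.28 ± 0.07 and RIPK2 at 0.18 ± 0.06. Cytosolic ribosomal protein genes moved up against other genes (camera adjusted p = 0.00134, and adjusted p = 0.633 with an estimated correlation). Of them 0 of 56 passed on either count, and their direction turned without replicate 1 (adjusted p 0.241). The median of all genes was -0.048 log2 per h. The list medians lay near 0, at 0.003 for ribosomal protein genes, 0.007 for cell cycle regulators, 0.0075 for phosphatase, ubiquitin and small GTPase regulators and 0.018 for NF-kappa-B pathway genes. The other 16 lists did not pass, and of their members ID1, ITGAM, ZNF35 and ZNF506 are those named above. The NF-kappa-B call ended under quantile normalization (0.183) and without replicate 1 (0.175), the cell cycle call without replicate 2 (0.36) and the ribosomal call under quantile normalization (0.361).

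The count of 26 was small and unstable. It was 102 after quantile normalization (88 higher), 225 after median scaling (202 higher), 112 without further scaling (81 higher), 10 with ribosomal protein genes as the reference, 58 with array weights, 2 without the batch term and 0 with free intercepts, where limma gave 1019 probe sets at an unadjusted p of 0.05. Leaving out single arrays gave 98 (GSH at 180 min replicate 1), 62 (GSNO at 180 min replicate 4), 52 (GSH at 90 min replicate 4), 41 (SB with GSNO at 180 min replicate 1), 15 (GSH at 180 min replicate 3) and 15 (GSNO at 180 min replicate 2). Without the 9 arrays of high 3' to 5' ratio it was 62, with 47 higher, and without batch 4 it was 158, of which 115 were lower. It was 43 without batch 1, 5 without batch 2 and 15 without batch 3.

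With SB, the comparison of GSNO with GSH asked whether nitric oxide changes transcript loss while p38 is inhibited. Directions are those of the samples as labelled, and an exchange of the GSH and GSNO labels in this arm would turn them. Of the 397 probe sets that passed, 384 had a lower slope with GSNO. SIAH2 fell faster by -0.63 ± 0.10 log2 per h (adjusted p = 7.16e-05), PPP3CC by -0.54 ± 0.07 (adjusted p = 3.18e-06), and PELI1, a ubiquitin ligase of Toll-like receptor signalling, by -0.56 ± 0.09 (adjusted p = 0.000172), each with less left in 4 of 4 batches. PELI1 was left at 9.79% ± 3.27 with SB and GSNO against 37.4% ± 19.9 with SB and GSH. CDC25A, a phosphatase that drives the cell cycle, was left at 10.9% ± 9.89 against 36.0% ± 12.8, and the kinase STK17A at 13.7% ± 7.76 against 38.7% ± 26.3. MAP1S, FHL2, GABPB1, TUBGCP3, CBR3, TAF5 and ICOSLG also had lower slopes. Of other bright probe sets, those of PPP3CC had 0.03 and -0.29, and 1 of ICOSLG had 0.00. Genes with a higher slope were BTF3P11 (1.19 ± 0.28), RAG2 (1.02 ± 0.28), RNF6, MYEF2, HCG9, SMAD6, TAL1 and ATP4B. They were named without the filter on signal since fewer than 5 passed it, and RNF6 had -0.16 on another probe set, which was bright.

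In this comparison 8 lists moved down and 5 up against other genes, and without replicate 4 the calls ended for 4 of these 8 and for all 5. At 180 min the 3' to 5' ratio was above 1.5 on 2 arrays with SB and GSH and on 2 with SB and GSNO. Of 33 protein phosphatase, ubiquitin and small GTPase regulators 4 fell faster (10 adjusted over the list alone) and 0 more slowly: USP1 (-0.36 ± 0.05), SIAH2, PELI1 and RHOG (-0.16 ± 0.04), with a camera adjusted p of 1.74e-05 and adjusted p = 0.0824 with an estimated correlation. Of 34 NF-kappa-B pathway genes 4 fell faster (10 adjusted over the list alone), RIPK2 (-0.29 ± 0.06), NFKBIE (-0.26 ± 0.06), TRAF1 (-0.22 ± 0.06) and TBK1 (-0.22 ± 0.06), with an adjusted p of 0.000103 and adjusted p = 0.264 with an estimated correlation. Of 48 cell cycle regulators 5 fell faster (8 adjusted over the list alone), with CDC25A at -0.58 ± 0.12, PLK3 at -0.43 ± 0.10, AURKA at -0.24 ± 0.07 and CCNE1 at -0.22 ± 0.07 (adjusted p = 0.000759, and adjusted p = 0.286 with an estimated correlation). Apoptosis regulators passed with 3 of 41 falling faster (9 adjusted over the list alone), BCL2A1, an NF-kappa-B target that blocks apoptosis, at -0.28 ± 0.04, BNIP1 at -0.23 ± 0.05 and TNFRSF1A at -0.35 ± 0.08 (adjusted p = 0.00826, and adjusted p = 0.286 with an estimated correlation). MAPK phosphatases and ERK feedback inhibitors passed with 2 of 15 (3 adjusted over the list alone), SPRED2 at -0.29 ± 0.07 and DUSP7 at -0.39 ± 0.10 (adjusted p = 0.00962, and adjusted p = 0.286 with an estimated correlation). For mRNA-binding factors the count was 6 of 45 (9 falling faster and 1 more slowly adjusted over the list alone), PCBP1 at -0.20 ± 0.04 and FXR1 at -0.13 ± 0.03 (adjusted p = 0.0368, and adjusted p = 0.421 with an estimated correlation). For immediate-early transcription factors it was 3 of 36 (5 adjusted over the list alone), CEBPD at -0.28 ± 0.06 and JUND at -0.18 ± 0.05 (adjusted p = 0.0389, and adjusted p = 0.508 with an estimated correlation). For heat shock proteins it was 1 of 25 (4 adjusted over the list alone), DNAJA1 at -0.14 ± 0.04 (adjusted p = 0.0813, and adjusted p = 0.286 with an estimated correlation). XBP1 (-0.33 ± 0.06) and LDHA (-0.20 ± 0.04) fell faster, although the stress list and the glycolysis list to which they belong did not pass (adjusted p = 0.192 and 0.445). Alternatives ended the calls of the immediate-early factors (adjusted p 0.107 to 0.299), the mRNA-binding factors (0.116 to 0.299) and the heat shock proteins (0.107 to 0.351), each without replicate 3 or 4 and without the arrays of high 3' to 5' ratio among others. That of the apoptosis regulators ended without replicate 4 (0.1).

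Other groups moved up against the rest with SB, without a passing member on either count. These were the 56 ribosomal protein genes (median 0.04 log2 per h, camera adjusted p = 9.21e-09, and adjusted p = 0.287 with an estimated correlation), the 66 oxidative phosphorylation subunits (0.04, adjusted p = 2.93e-05, and adjusted p = 0.264 with an estimated correlation) and the 31 monocyte markers (0.02, adjusted p = 0.00485, and adjusted p = 0.0824 with an estimated correlation). So did the 24 housekeeping genes (0.02, adjusted p = 0.0335, and adjusted p = 0.424 with an estimated correlation), whose direction turned after quantile normalization (adjusted p 0.98). The 25 markers of other cell types had a median of 0.03 (adjusted p = 0.0738, and adjusted p = 0.421 with an estimated correlation). The ribosomal call ended under quantile normalization (adjusted p 0.204) and without replicate 4 (adjusted p 0.431). Without replicate 4 the oxidative phosphorylation (0.13), monocyte (0.146), housekeeping (0.795) and other cell type calls (0.518) ended too, and that of the other cell types also under quantile normalization (0.208), median scaling (0.19) and no further scaling (0.144).

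In limma 397 probe sets of 343 genes passed, 384 with a lower slope and 13 with a higher one, and 374 of the 384 fell in at least 1 condition. Without SB, 83.1% of the 384 had a positive GSNO effect. The count was 121 without SB with GSH at 180 min replicate 4, 148 without SB with GSNO at 180 min replicate 4 and 1008 without SB with GSNO at 180 min replicate 3. It was 221 after quantile normalization, 172 after median scaling, 213 with ribosomal protein genes as the reference, 95 without the batch term and 1 with free intercepts. Without batch 2, 3 or 4 it was 168, 794 or 59. Without the 9 arrays of high 3' to 5' ratio 239 passed, 227 of them lower.

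**Figure D3:**
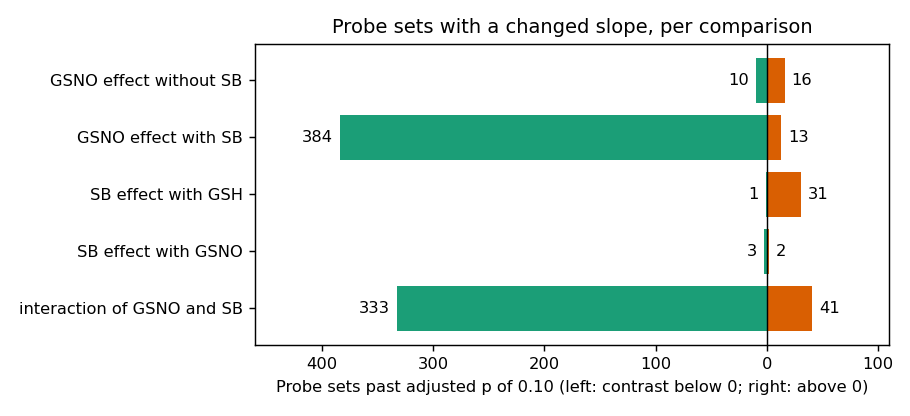
Number of probe sets that passed in each comparison, with higher slopes to the right and lower slopes to the left of the zero line. GSNO gave 16 higher and 10 lower slopes without SB, and 13 higher and 384 lower slopes with SB.

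The effect of GSNO was then tested for a difference between the SB arms, with the labels of both arms taken as given. SIAH2 differed by -1.22 ± 0.14 log2 per h (adjusted p = 1.08e-07), PELI1 by -0.86 ± 0.13 (adjusted p = 3.01e-05), STK17A by -0.76 ± 0.11, PPP3CC by -0.72 ± 0.10 and the stress kinase PLK3 by -0.82 ± 0.13. LCP2, an adaptor of immune receptors (-1.03 ± 0.24), CDC25A (-0.997 ± 0.18), RIOK2 (-0.92 ± 0.16), TRAF3IP2, an adaptor of IL-17 signalling (-0.82 ± 0.15), GABPB1, TTLL4 and MAP1S differed in the same direction. SIAH2 and PELI1 had more left with GSNO in 4 of 4 batches without SB and in 0 of 4 with SB. JAM2 (0.71 ± 0.21), TAGLN3 (0.52 ± 0.11), NAT9, ZNF35, PNISR, PCDH7, DHX32, LAMA5, ANKRA2, SLC7A6, PRPF19 and ZNF692 had the largest positive differences among genes that met the naming rule for the interaction. Another bright probe set of PPP3CC had 0.16 and another of PLK3 had 0.01, unlike the probe sets named. Those of CDC25A, GABPB1, STK17A and TTLL4 had -0.49, -0.21, -0.23 and -0.07, smaller in size than the probe sets named.

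Gene groups differed as well. Of 33 protein phosphatase, ubiquitin and small GTPase regulators 5 differed downward and 0 upward (8 and 0 adjusted over the list alone), with USP1 at -0.49 ± 0.08 and RHOG at -0.28 ± 0.06 beside SIAH2 and PELI1. The camera adjusted p was 6.21e-06, and adjusted p = 0.0982 with an estimated correlation. Of 34 NF-kappa-B pathway genes 4 differed downward (11 adjusted over the list alone), namely RIPK2 (-0.47 ± 0.08), RELB (-0.47 ± 0.11), NFKBIE (-0.36 ± 0.09) and RELA (-0.21 ± 0.06). Of 48 cell cycle regulators 3 did (4 adjusted over the list alone), PLK3, CDC25A and CCNE1 (-0.43 ± 0.09). Both lists had a camera adjusted p of 2.83e-05, and adjusted p = 0.157 and adjusted p = 0.204 with an estimated correlation. Among 41 apoptosis regulators 4 differed downward (4 adjusted over the list alone), BCL2A1 at -0.39 ± 0.06, TNFRSF1A at -0.65 ± 0.12, BNIP1 at -0.33 ± 0.07 and BIK at -0.51 ± 0.14, with adjusted p = 0.0134 and adjusted p = 0.289 with an estimated correlation. Of 45 mRNA-binding factors 4 differed downward (7 downward and 1 upward adjusted over the list alone; adjusted p = 0.0159, and adjusted p = 0.367 with an estimated correlation), PCBP1 at -0.35 ± 0.06. Of 15 MAPK phosphatases 2 did (2 adjusted over the list alone), DUSP7 at -0.66 ± 0.14 and SPRED2 at -0.38 ± 0.10, and of 25 heat shock proteins 1 did (2 adjusted over the list alone), STIP1 at -0.30 ± 0.07. These lists had a camera adjusted p of 0.0433 each (adjusted p = 0.449 and adjusted p = 0.157 with an estimated correlation). Of 36 immediate-early factors 2 did (5 downward and 1 upward adjusted over the list alone), JUND at -0.34 ± 0.07 and CEBPD at -0.39 ± 0.09 (adjusted p = 0.0614, and adjusted p = 0.561 with an estimated correlation). Monocyte markers and oxidative phosphorylation subunits differed upward without a passing member on either count (adjusted p = 0.0433 and 0.0598, and adjusted p = 0.157 and adjusted p = 0.551 with an estimated correlation). At 180 min the 3' to 5' ratio was above 1.5 on 2 SB arrays with GSH and 2 with GSNO, and on 1 array without SB. KEAP1 (-0.55 ± 0.11), XBP1 (-0.39 ± 0.09) and LDHA (-0.35 ± 0.06) differed too, in lists that did not pass (adjusted p = 0.712, 0.316 and 0.219). Above the median signal alone the calls of the apoptosis regulators (0.137), mRNA-binding factors (0.109), MAPK phosphatases, heat shock proteins and immediate-early factors (0.157 each) ended. Median scaling ended those of the immediate-early factors (0.102), monocyte markers (0.13) and oxidative phosphorylation subunits (0.537).

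The interaction passed for 374 probe sets of 316 genes in limma, 333 lower and 41 higher. All 13 probe sets called for GSNO in both arms had a higher slope without SB and a lower one with SB. Across the 11107 probe sets above the median signal, the GSNO effects of the arms had a Pearson correlation of -0.244 and a Spearman correlation of -0.193, and a Pearson correlation of -0.321 across the 3583 of them that fell. These are correlations across genes, which are not independent replicates. In 100 exchanges of GSNO and GSH at random within time and batch the Pearson correlation ranged from -0.32 to 0.277 around a median of -0.0136, and 6 were as far from 0 as the observed value. The count was 600 after median scaling, 157 without the batch term, 131 without batch 2 and 26 with free intercepts. Lower and higher ones numbered 450 and 64 without batch 1, 119 and 12 without batch 2, 354 and 17 without batch 3, and 164 and 87 without batch 4.

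**Figure D4:**
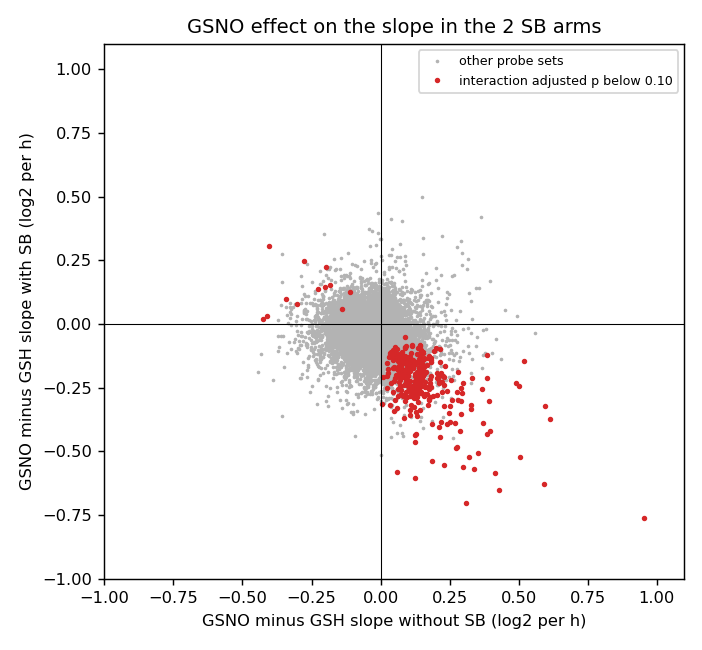
GSNO effect on the slope (log2 per h) with SB against that without SB for the 11107 probe sets above the median signal, with the 326 that had an interaction marked. Their correlation is -0.244, and SIAH2 lies at 0.59 without SB and -0.63 with SB.

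The comparison of SB with no SB in GSH asked whether p38 inhibition alters loss in the absence of nitric oxide. It holds only if the GSH and GSNO labels of both SB arms are right. Of the 32 probe sets that passed, 31 had a higher slope with SB. RNF19B, a ubiquitin ligase, had a slope higher by 1.00 ± 0.21 log2 per h (adjusted p = 0.022), with 34.0% ± 34.4 left against 4.76% ± 5.69. SIAH2 was higher by 0.75 ± 0.14 (adjusted p = 0.0108), CRKL by 0.66 ± 0.12 (adjusted p = 0.0108), KEAP1, the sensor that restrains NRF2, by 0.52 ± 0.11 (adjusted p = 0.022) and the deubiquitinase USP1 by 0.44 ± 0.08 (adjusted p = 0.00723), each with more left in 4 of 4 batches. RIOK2, DUSP7, a phosphatase of ERK (0.65 ± 0.14), TTLL4, TRIM24, PELI1 (0.56 ± 0.13), ZFAND5 and POLA2 were also higher. DICER1, the nuclease of microRNA maturation, was the single gene with a lower slope (-0.36 ± 0.09, adjusted p = 0.0879). Other bright probe sets had -0.02 for USP1, 0.05 for CRKL, 0.03 for TTLL4 and 0.06 for TRIM24, while those of RNF19B and ZFAND5 had 0.41 and 0.37.

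At 180 min with GSH the 3' to 5' ratio was above 1.5 on 2 arrays with SB and on 1 without, beside the following groups. Of 33 protein phosphatase, ubiquitin and small GTPase regulators USP1, SIAH2 and PELI1 passed, all higher (5 adjusted over the list alone; camera adjusted p = 0.0009, and adjusted p = 0.304 with an estimated correlation). Of 48 cell cycle regulators CCNG1 passed (0.25 ± 0.06; 2 adjusted over the list alone; adjusted p = 0.000405, and adjusted p = 0.366 with an estimated correlation). The immediate-early factors and the mRNA-binding factors moved up without a passing member over all probe sets, with 4 and 2 higher when adjusted over the list alone. CEBPB had 0.40 ± 0.12 and ZFP36L2 0.40 ± 0.11, and both lists had a camera adjusted p of 0.00796 (adjusted p = 0.534 and adjusted p = 0.366 with an estimated correlation). NF-kappa-B pathway genes, with 0 passing and 2 higher adjusted over the list alone, and MAPK phosphatases, with DUSP7 passing and 2 higher adjusted over the list alone, moved up with an adjusted p of 0.0203 each (adjusted p = 0.489 and adjusted p = 0.419 with an estimated correlation). Monocyte markers moved down without a passing member (adjusted p = 0.0474, and adjusted p = 0.304 with an estimated correlation). So did ribosomal protein genes (adjusted p = 0.0602, and adjusted p = 0.891 with an estimated correlation), whose direction turned without replicate 2 (adjusted p 0.618). LDHA rose relative to its slope without SB by 0.30 ± 0.06 (adjusted p = 0.0176). Without the 9 arrays of high 3' to 5' ratio the calls ended for the immediate-early factors and MAPK phosphatases (0.436 each), mRNA-binding factors (0.338), monocyte markers (0.567) and ribosomal protein genes (0.85). The calls of monocyte markers and ribosomal protein genes also ended under quantile normalization (0.122 and 0.866), median scaling (0.159 and 0.221) and ribosomal protein scaling (0.113 and 0.182).

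In limma 32 probe sets of 30 genes passed, 31 higher and 1 lower, and 25 of the 32 also fell faster with GSNO in the SB arm, which uses the same SB with GSH arrays. The count was 3 without SB with GSH at 180 min replicate 4, 54 without SB with GSH at 180 min replicate 1, 78 without SB with GSNO at 180 min replicate 4 and 21 without SB at time 0 replicate 1. Of arrays without SB, leaving out GSH at 180 min replicate 1, 2 or 4 gave 69, 11 or 13, and leaving out GSNO at 45 min replicate 2 gave 21. It was 72 after quantile normalization, 54 without further scaling, 11 with ribosomal protein genes as the reference, 59 above the median signal, 20 with array weights, 6 with free intercepts, 6 without the 9 arrays of high 3' to 5' ratio and 13 with the beta-actin ratio as a covariate. No probe set passed without the batch term (limma, 909 at an unadjusted p of 0.05) or without batch 2 (1160), 1 passed without batch 4 and 65 without batch 1.

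The comparison of SB with no SB in GSNO asked whether p38 inhibition alters loss when nitric oxide is present, again with the labels of both SB arms taken as given. CYTH2 fell faster with SB by -0.61 ± 0.10 log2 per h (adjusted p = 0.00269), to 25.4% ± 11.3 left against 102% ± 16.4. ADRM1, a ubiquitin receptor of the proteasome (-0.26 ± 0.05, adjusted p = 0.0393), and the chemokine CCL4 (-0.37 ± 0.08, adjusted p = 0.0829) also fell faster, with CCL4 left at 46.0% ± 14.3 against 95.4% ± 18.5. CDK13 (0.99 ± 0.21) and ZKSCAN4 (0.90 ± 0.19) had higher slopes (adjusted p = 0.0829 each). Both lay below the median signal and were named without the filter on signal, while a bright probe set of CDK13 had -0.05. At 180 min with GSNO the 3' to 5' ratio was above 1.5 on 2 arrays with SB and on 0 without. NF-kappa-B pathway genes moved down with 0 of 34 passing on either count, RELB at -0.27 ± 0.11 (camera adjusted p = 0.0669). Apoptosis regulators did so with 0 of 41 passing (3 falling faster adjusted over the list alone), BIK at -0.59 ± 0.14. The protein phosphatase, ubiquitin and small GTPase regulators did so with 0 of 33 passing (1 adjusted over the list alone), SIAH2 at -0.47 ± 0.14. The last 2 lists had an adjusted p of 0.0876, and all 3 calls were lost with an estimated correlation (adjusted p = 0.893 with an estimated correlation for each) and under quantile normalization (0.156 for each). In limma 5 probe sets passed, 2 higher and 3 lower, with 1483 at an unadjusted p of 0.05. Leaving out single arrays gave between 1 (GSNO at 180 min replicate 2) and 12 (SB with GSH at 45 min replicate 1), with 23 of the 56 arrays moving the count by more than 1.5 times, and it was 27 without the 9 arrays of high 3' to 5' ratio. It was 1 without batch 1, 1 without batch 3, 10 without batch 4 and 0 without batch 2 (limma, 1354 at an unadjusted p of 0.05).

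At time 0, after 30 min of actinomycin D, the comparison of SB with no SB asked whether levels already differed. None of the 22215 probe sets passed in limma (1216 at an unadjusted p of 0.05). The immediate-early gene NR4A1 had 1.15 ± 0.25 log2 with SB (adjusted p = 0.859), and it alone of 36 immediate-early transcription factors was higher when adjusted over the list alone. This list moved up in camera (adjusted p = 0.079, and adjusted p = 0.744 with an estimated correlation), with KLF6 at 0.66 ± 0.25. NF-kappa-B pathway genes moved up with 0 of 34 passing on either count (adjusted p = 0.0188, and adjusted p = 0.744 with an estimated correlation), NFKBIA at 0.28 ± 0.11 and NFKB2 at -0.45 ± 0.11. The 66 oxidative phosphorylation subunits moved down with a median of -0.08 and 0 passing on either count (adjusted p = 2.57e-06, and adjusted p = 0.744 with an estimated correlation), COX5B at -0.39 ± 0.13. This call ended without replicate 4 (adjusted p 0.158), whose SB array at time 0 had a beta-actin ratio of 1.9. Ribosomal protein genes moved down with 0 of 56 passing on either count (adjusted p = 0.0679, and adjusted p = 0.867 with an estimated correlation), RPS19 at -0.23 ± 0.10. Quantile normalization ended the calls of the immediate-early factors (0.156) and ribosomal protein genes (0.129), and the mean of all probe sets of a gene that of the NF-kappa-B pathway genes (0.162). SIAH2 and DUSP1 had 0.22 ± 0.11 and 0.81 ± 0.45.

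Levels at each time described the course behind these slopes. For ALAS1 the difference of GSNO from GSH without SB was 0.18 log2 at 45 min, 0.43 at 90 min and 0.69 at 180 min, and with SB it was -0.17, -0.45 and -0.77. For SIAH2 without SB it was 0.06, 1.09 and 1.76, and with SB 0.18, -0.58 and -2.22. In limma no probe set differed at 45 min (1574 without SB and 638 with SB at an unadjusted p of 0.05) or at 90 min (876 and 744). At 180 min 14 differed without SB, 9 higher and 5 lower, and 223 differed with SB, 7 higher and 216 lower.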

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

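The tests of scaling, of shared calls, of a full exchange of labels in 1 SB arm and of other splits of the arrays were chosen after the results were seen. Those of labels in single batches, of dim signals and of RNA quality in the SB effect with GSH were chosen before.

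Single arrays stood apart from the other 3 of their group in 11 of 116 groups tested, where chance gives about 1 in 20, or 5.8. The 678th highest signal was 1172 for SB with GSNO at 45 min replicate 3. The median signal was 33.6 at time 0 without SB replicate 3 and 34.2 for SB with GSH at 180 min replicate 4. The 3' to 5' ratio of GAPDH was 2.17 for GSH at 45 min replicate 4 and 1.54 for GSH at 180 min replicate 3, both without SB, and 2.87 for SB with GSH at 45 min replicate 1. That of beta-actin was 7.29 for GSH at 45 min replicate 4 and 1.7 for GSNO at 90 min replicate 3 without SB, and 1.9 for SB at time 0 replicate 4 and 2.13 for SB with GSH at 45 min replicate 1. For MYC, 29.3% was left with SB and GSNO in replicate 2.

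The effect of GSNO on the slope differed between the SB arms for 374 probe sets by the interaction test in limma. Among the genes named in any comparison, differences were negative for SIAH2 (-1.22 log2 per h), LCP2 (-1.03), CDC25A (-0.997), EXOSC4 (-0.983), RIOK2 (-0.917), PELI1 (-0.86), PLK3 (-0.818), TRAF3IP2 (-0.815), GABPB1 (-0.784), TTLL4 (-0.762), STK17A (-0.76), MAP1S (-0.728), PPP3CC (-0.723), RNF19B (-0.692), MEF2D (-0.665), TAF5 (-0.659), FHL2 (-0.641), CEBPA (-0.621), QRSL1 (-0.594), TUBGCP3 (-0.589), RFC1 (-0.559), MRPS2 (-0.541), ALAS1 (-0.505), SCCPDH (-0.467) and MRPL58 (-0.398). They were positive for MYEF2 (1.3), CDK13 (0.904), SMAD6 (0.834), JAM2 (0.709), ACTN3 (0.535), TAGLN3 (0.524), NAT9 (0.448), ZNF35 (0.443), PNISR (0.441), PCDH7 (0.419), DHX32 (0.382), LAMA5 (0.363), ANKRA2 (0.348), SLC7A6 (0.334), PRPF19 (0.236) and ZNF692 (0.198). In camera 8 lists differed downward: the phosphatase, ubiquitin and GTPase regulators (adjusted p = 6.21e-06), NF-kappa-B pathway genes and cell cycle regulators (2.83e-05 each), apoptosis regulators (0.0134), mRNA-binding factors (0.0159), MAPK phosphatases and heat shock proteins (0.0433 each) and immediate-early factors (0.0614). Monocyte markers (0.0433) and oxidative phosphorylation subunits (0.0598) differed upward. With an estimated correlation the first list alone passed (adjusted p = 0.0982).

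The opposite GSNO effects in the SB arms were weighed first. Against RNA quality as the whole cause, 261 of the 374 probe sets were also called without the 9 arrays of high 3' to 5' ratio, and against scaling at least 251 were called under each other scaling. For probe sets called from 3 batches, the median interaction in the batch left out was -0.0965, -0.397, -0.124 and -0.467; all lie below 0, but those of batches 1 and 3 are within their SD of 0.188. In batch 1 the median GSNO effects were -0.0161 without SB and -0.111 with SB, so not of opposite sign, while in the other batches they were positive without and negative with SB; exchanged labels in some batches stay open. An exchange of the GSH and GSNO labels throughout 1 SB arm cannot be told apart from an effect of SB, since it gives the same 4 slopes under other names and turns the correlation of the effects to 0.244. After it, the 333 probe sets with a lower interaction would have GSNO effects of the same sign in both arms. The samples are listed with GSH before GSNO without SB and with GSNO before GSH with SB, an order that decides nothing by itself. An effect of p38 inhibition on the response to nitric oxide also stays open, and no measurement here separates it from such an exchange.

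Signals that rose after transcription was blocked were weighed next. Of 1077 rising probe sets 865 lost their call under at least 1 scaling, which scaling may explain, while 212 were called under all 5. The call was kept by 956 under quantile normalization, 973 under median scaling, 1077 without further scaling and 219 with ribosomal protein genes as the reference. Most losses thus came with the ribosomal protein reference. Of the 1077, 71.2% lay above the median signal, but so did 3078 of all 3928 probe sets called with GSH, falling or rising. Calls lie mostly among brighter probe sets in any case, so this share does not decide on dim background. All 5 scalings are relative to other transcripts and total mRNA per cell was not measured, so neither a rise nor a fall relative to the reference is shown to be one per cell.

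The slower fall with SB and GSH was weighed last. For the 32 called probe sets the median difference was 0.372 log2 per h (median SE 0.0832) with all arrays and 0.295 (median SE 0.091) without the 9 arrays of high ratio, where 6 were still called; the calls ended with a smaller difference and a larger error. RNA quality therefore stays open as part of it. An effect of p38 inhibition on transcript loss also stays open.

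Other splits of the arrays were counted, 100 for each comparison of slopes with the real one included. For the fall with GSH 1 split gave as many falling probe sets (2851 for the real one, 1496 at most in the others). For any difference among the slopes 2 did (284 and 312), for the GSNO effect without SB 2 (26 and 38) and for the GSNO effect with SB 1 (397 and 351). The share was below 0.05 for each of these 4, with no adjustment for the number of comparisons. For 2 of them another split gave more than the real one, and shares from 100 splits are coarse. Chance could not be excluded for the SB effect with GSH (7 splits; 32 and 134), the SB effect with GSNO (22 splits; 5 and 450) or the interaction (6 splits; 374 and 721). More than 3 times the real count was called by 14 splits for the SB effect with GSNO, which points to a structure of the samples, and by 1 for the SB effect with GSH; its source was not tested. At time 0 all 32 splits gave at least the real count of 0 (limma, 1216 at an unadjusted p of 0.05), and the highest other gave 9.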

How the results depend on the processing

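Counts of probe sets that passed are given for each alternative under which they moved by more than 1.5 times; the cause was not tested except where stated. The 2 RNA quality settings and the single arrays left out were chosen after the data were seen. For the fall with GSH (2851 falling) free intercepts moved the count of falling probe sets, to 1874; with no replicate block it was 2088, and 384 rose in place of 1077. Rising ones also numbered 299 with free intercepts, 648 at a threshold of 0.05, 2369 with quantile normalization, 2127 without further scaling, 219 with ribosomal protein scaling, 527 without replicate 2 and 606 without replicate 3. For any difference among the slopes (284) it was 163 with ribosomal protein scaling, 81 with no replicate block, 4 with free intercepts and 150 for levels at 180 min, and 103 to 306 without each batch. For the GSNO effect without SB (26) it was 102 with quantile normalization, 225 with median scaling, 112 without further scaling, 10 with ribosomal protein scaling, 2 with no replicate block, 58 with array weights, 0 with free intercepts (limma, 1019 at an unadjusted p of 0.05), 14 for levels at 180 min, 15 at a threshold of 0.05, 62 without the arrays of high 3' to 5' ratio, 43 with the beta-actin ratio as covariate, and 5 to 158 without each batch. For the GSNO effect with SB (397) it was 221 (quantile), 172 (median), 213 (ribosomal), 95 (no block), 1 (free intercepts), 223 (levels), 259 (threshold), 239 (high ratios out) and 59 to 794 (batches). For the SB effect with GSH (32) it was 72 (quantile), 54 (no further scaling), 11 (ribosomal), 59 (above the median signal, where fewer probe sets are tested), 0 (no block; limma, 909 at an unadjusted p of 0.05), 20 (weights), 6 (free intercepts), 6 (levels), 15 (threshold), 6 (high ratios out), 13 (covariate) and 0 to 65 (batches). For the SB effect with GSNO (5) it was 3 (quantile), 10 (median), 2 (ribosomal), 2 (offset), 3 (above the median signal), 2 (no moderation), 1 (no block), 3 (block per SB arm), 0 (free intercepts; limma, 1481 at an unadjusted p of 0.05), 2 (levels), 2 (threshold), 27 (high ratios out) and 0 to 10 (batches). For the interaction (374) it was 600 (median), 157 (no block), 26 (free intercepts) and 131 to 514 (batches). The count of 0 at time 0 (limma, 1216 at an unadjusted p of 0.05) was 0 in all alternatives run. Results for genes named kept their direction under each alternative run for them, which did not include single arrays left out. In several of these the direction could not turn. The naming rule fixed it where a batch was left out. Tests without moderation, the threshold of 0.05, the signal filter (run for 92 results) and the changes of batch term leave the slopes as they are. Of 107, between 22 (free intercepts) and 104 (no further scaling) stayed past the threshold, 43 with no replicate block and 63 without the arrays of high ratio. Of 56 list results past the threshold, between 36 (without replicate 4) and 56 (offset) stayed so. In 4 cases the direction turned: ribosomal proteins in the fall with GSH under quantile normalization (adjusted p 0.391), in the GSNO effect without SB without replicate 1 (0.241; range without each batch 3.11e-10 to 0.241) and in the SB effect with GSH without replicate 2 (0.618; range 3.28e-06 to 0.867), and housekeeping genes in the GSNO effect with SB under quantile normalization (0.98). The correlation of the GSNO effects, -0.244 (jackknife error 0.148), was -0.326 to -0.134 over the alternatives, all within that error. The error was itself computed from the fits without each batch. Median scaling, no further scaling, ribosomal protein scaling, the signal filter and the changes of batch term could not move this correlation. They shift all probe sets alike or leave the slopes as they are. Probe sets below the median signal give little precision.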
